A study of Oryza sativa with 4 samples.

How the data were processed

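RNA sequencing libraries from seedlings of rice strain Taibei 309 were analysed, 2 from the wild type (WT) and 2 from the panda mutant, grouped by the genotype in the labels. Reads were aligned with HISAT2 and quantified with StringTie, per the submitters' processing notes, and the HISAT2 version is not given in the sources used here. The deposited tables come from StringTie 1.3.4d run with the option that measures annotated transcripts and assembles none, per the file headers. The annotation is called rice7 in those headers and uses identifiers that start with LOC_Os. Beyond that name the genome build is not given in the sources used here. No strand option stands in the StringTie command, so the libraries were read as unstranded, and levels of antisense or overlapping genes, and of near-identical copies such as tandem duplicates, are uncertain.

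Each deposited table lists 66153 transcripts of 55801 genes on the 12 chromosomes. For every transcript it gives TPM (transcript abundance scaled to a fixed total per library), the related measure FPKM and the mean coverage per base, other values than counts, all as deposited by the authors. TPM has the same total in every library, 1000000, per the values in the deposited files. Gene levels were computed as the sum of the TPM of a gene's transcripts. Columns that could not be tied to a sample numbered 0. Files were tied to samples by the record of deposited files. The command lines in the file headers name the WT libraries TP and the panda libraries DL, with the replicate numbers of the labels. What these letters stand for is not given in the sources used here, and DL there was not taken to mean the gene of that name.

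Depth was computed from the deposited coverage and transcript lengths. The libraries held 8.54, 6.98, 6.03 and 9.09 Gb on transcripts (WT replicates 1 and 2, then panda replicates 1 and 2). With an assumed 300 bases per read pair, a level of 1 TPM on 1 kb of transcript rests on 12.0 (panda replicate 1) to 18.2 pairs (panda replicate 2).

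Genes with at least 1 TPM in at least 2 libraries were tested (22220 genes). The test was limma (version 3.58.1, with statmod 1.5.0, in R 4.3.3) on log2(TPM + 1), with a spread that follows the mean level, no replicate block, and two-sided p-values adjusted by the Benjamini-Hochberg method to a threshold of 0.05. A fold change is on the log2(TPM + 1) scale, which understates the change of genes with low levels. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so all calls rest on limma's pooling of the spread across genes. Gene lists were tested with camera (limma, preset correlation 0.01, lists with at least 3 measured members, adjusted over 29 lists) and again with a correlation estimated per list. Runs of neighbours were tested by counting adjacent pairs of tested genes changed in the same direction, against 10000 shuffles of the calls, one-sided. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

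Neither the deposited tables nor the reference table (NCBI RefSeq genes of the rice assembly ASM3414082v1) pair LOC_Os identifiers with gene names. Names therefore come from pairs of identifier and symbol written down from general knowledge. A pair was used only if the reference table lists the symbol on the same chromosome and the positions agree between both assemblies: within 10 kb of the shift seen for neighbouring pairs, or a gene span within 5% of the reference gene's. Of 529 loci, 440 passed this check, and 337 of these met the 5% bound. For 62 the symbol was not found in the reference table, and 24 lay elsewhere. A further 3 loci are not analysed here. A pair that passes can still name a close neighbour by mistake.

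Of the lists, 6 were fixed before the data were examined, with 44 of their 70 loci used. A further 24 lists that were to be drawn from gene descriptions could not be built, since no descriptions were at hand. In their place 24 lists of single genes (420 of 483 loci used) were written after the tables were opened and before any difference was computed. Named genes follow a rule fixed before the data were examined and adapted where gene descriptions were missing. It took all measured polycomb and STMADS11-clade genes, and members of the other early lists that passed (at most 6 per list). Among genes with a name that passed, and whose WT and panda libraries did not overlap, it took the 10 largest increases and 10 largest decreases. It also took up to 4 genes of smallest p from each other list with a call. That clause was written for the lists from gene descriptions, and was applied to the 24 lists that took their place. Names were to come from reference descriptions or symbols, and came from the checked pairs instead. With these changes the rule named 85 genes. Other names were chosen after their values were seen, as the text says where they appear.

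The procedure was tested on simulated data with the spread of these libraries and 200 of 22220 genes changed. It recovered 37.3% of genes changed by 0.5 on the log2 scale, 97% of those changed by 1 and 98.5% of those changed by 2. The changed genes were drawn from genes at higher WT levels, so recovery of genes with low levels was not measured. Of its 183 calls, 28 (15.3%) were unchanged genes. Of 30 simulated lists it called the raised list and 0 unchanged lists. With an estimated correlation the raised list had an adjusted p of 0.19 in camera, so that version can miss a real shift where genes vary independently. Noise was drawn for each gene on its own. The simulation therefore cannot show how either version behaves where the genes of a list move together. The permutation test of neighbours gave p = 0.281 for scattered calls and 2e-04 with stretches of changed neighbours added.

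The alternatives were pseudocounts of 0.1 and 0.5 TPM, no filter and a filter of 5 TPM, median-ratio and quantile scaling, FPKM, limma without the trend and with robust moderation, limma-voom on estimated read pairs, the replicate number as a block, each library left out in turn, and an absolute log2 fold change of at least 1. They were chosen before the data were examined. A block with the replicate numbers crossed, a count of neighbours that do not overlap, and a count of neighbours without the genes of dense runs (under 1.5 kb of chromosome per gene), were chosen after seeing the data. A rescaling to nuclear genes and a restriction to annotated transcripts would have changed nothing, since the tables hold 12 chromosomes and annotated transcripts only, and were left out.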

Results

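RNA was sequenced from seedlings of rice strain Taibei 309, in 2 wild-type (WT) libraries and 2 libraries of the panda mutant. The study asks how the protein PANDA controls gene expression, the histone mark set by polycomb proteins, and the balance of panicle number and grain size. The libraries held 8.54 and 6.98 Gb of aligned bases on transcripts in WT and 6.03 and 9.09 Gb in panda, which by estimate puts 12.0 to 18.2 read pairs behind a level of 1 TPM (transcript abundance scaled to the same total in every library) on a transcript of 1 kb. The labels give no locus for the mutated gene, so its level could not be checked and no gene is taken to be it. Nothing in the labels says that the replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

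MADS-box genes that are known from flowers rose from near silence in panda seedlings. OsMADS3, which specifies stamens, rose from 0.791 ± 0.112 TPM in WT to 28.9 ± 6.88 TPM in panda (SD, n = 2 each), a log2 fold change of 4.04 ± 0.18 (SE) with an adjusted p of 0.0013. The SEPALLATA-like genes OsMADS5 and OsMADS1, which act in floral organ and meristem identity, rose from 0.174 ± 0.017 to 4.58 ± 0.276 TPM and from 0.242 ± 0.226 to 3.24 ± 0.414 TPM (SD, n = 2 each). OsMADS14, an inflorescence identity gene, rose from 0.153 ± 0.0422 to 3.19 ± 0.0947 TPM (SD, n = 2). DL (DROOPING LEAF), a YABBY gene needed for carpels and the leaf midrib, rose from 2.62 ± 0.524 to 8.86 ± 0.271 TPM (SD, n = 2).

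Other flower genes stayed near 0, lay higher in panda at low levels without a call, or fell. OsMADS7 and OsMADS8 were listed at 0 in all 4 libraries, and OsMADS13 and OsMADS15 reached at most 0.0371 TPM in any. Hd3a, which encodes a florigen, was also listed at 0 in every library. OsMADS21 was listed at 0 and 0.0501 TPM in WT and at 0.898 and 0.47 TPM in panda, and OsMADS34 at 0.0459 and 0 TPM in WT and at 0.705 and 0.134 TPM in panda, both too low to be tested. These 7 genes were chosen after their values were seen. OsMADS16, a petal and stamen identity gene chosen after its values were seen, fell from 9.53 ± 0.488 to 5.88 ± 0.151 TPM (SD, n = 2; adjusted p = 0.026, and 0.058 without WT replicate 1). OsMADS58, the close relative of OsMADS3 and also chosen after its values were seen, measured 1.03 ± 0.0136 TPM in WT and 2.17 ± 0.306 TPM in panda (SD, n = 2; adjusted p = 0.053).

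OsMADS3 (LOC_Os01g10504) lies on chromosome 1 at 5559548 to 5568844, OsMADS14 (LOC_Os03g54160) on chromosome 3 at 31031146 to 31041569, and OsMADS5 (LOC_Os06g06750) on chromosome 6 at 3162801 to 3169415, in the positions of the deposited tables. The loci of OsMADS1 (LOC_Os03g11614, 6052750 to 6061369) and DL (LOC_Os03g11600, 6041245 to 6048687) are neighbours on chromosome 3.

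Of 31 listed MADS-box genes 17 were measured. Of the 17, 7 rose, 2 fell and 8 did not pass (9 and 2 adjusted over the list alone), with a median log2 fold change of 0.48. OsMADS3, OsMADS5, OsMADS14 and OsMADS1 were under 1 TPM in both WT libraries and passed the filter only through the panda libraries. The list as a whole was shifted up (camera, adjusted p = 5.1e-05), but adjusted p = 0.5 with an estimated correlation. With no filter its median was 0.13 (camera, adjusted p = 4.2e-05). OsMADS56, a flowering-time gene chosen after its values were seen, fell from 69.2 ± 4.95 to 33 ± 3.65 TPM (SD, n = 2; adjusted p = 0.0082), and OsMADS27, chosen in the same way, rose by 0.54 on the log2 scale (adjusted p = 0.061 with a replicate block, 0.055 in limma-voom, 0.055 without WT replicate 1 and 0.1 without WT replicate 2). Among the 3 STMADS11-clade genes, a list fixed before the data were examined, OsMADS55 rose from 7.61 ± 0.685 to 21.7 ± 0.448 TPM and OsMADS22 from 79.4 ± 2.89 to 119 ± 5.52 TPM, while OsMADS47 measured 48.6 ± 4.69 and 43 ± 1.02 TPM (SD, n = 2; adjusted p = 0.28). That list was shifted up with adjusted p = 0.035 and 2 members up adjusted over the list alone, with adjusted p = 0.5 with an estimated correlation, 0.06 with median-ratio scaling, 0.096 with quantile scaling and 0.06 with a replicate block. It was also lost without WT replicate 1 (adjusted p = 0.084) and without panda replicate 2 (0.055).

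Development genes of other families moved both ways. YAB1, a YABBY transcription factor gene, rose from 11.1 ± 1.29 to 30.4 ± 1.02 TPM, and OSH71, a class I KNOX homeobox gene, from 0.338 ± 0.143 to 2.21 ± 0.414 TPM (SD, n = 2). OsHox24, an HD-Zip homeobox gene, fell from 3.3 ± 0.254 to 0.528 ± 0.299 TPM (SD, n = 2). OSH10, OsHox1 and OsHox9, chosen after their values were seen, fell by 0.61, 0.4 and 0.42 on the log2 scale, but all 3 calls were lost with median-ratio scaling (adjusted p = 0.068, 0.077 and 0.07), with quantile scaling (0.095, 0.091 and 0.076) and without WT replicate 1 (0.1, 0.075 and 0.074). OSH10 and OsHox9 were also lost with a replicate block (0.071 and 0.058), OsHox9 without WT replicate 2 (0.11), OsHox1 and OsHox9 without the trend (0.073 and 0.083), OsHox9 with a pseudocount of 0.1 TPM (0.051), OSH10 and OsHox9 with FPKM (0.052 and 0.053), and OSH10 in limma-voom (0.12). With 3 genes up and 4 down of 17 (5 and 4 adjusted over the list alone), the homeobox and meristem list was not shifted as a whole (median 0.02, adjusted p = 0.16).

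**Figure D1:**
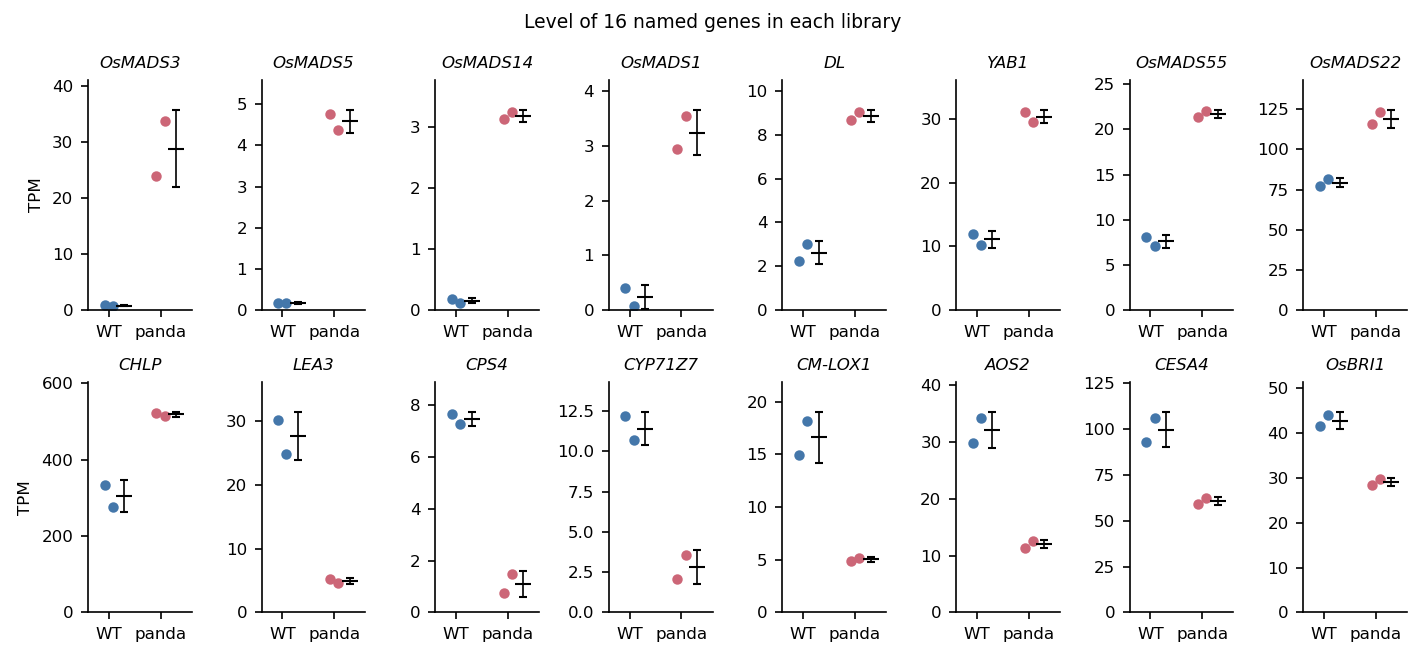
Level of 16 named genes in TPM in each library, WT in blue and panda in red, with the mean and SD (n = 2) beside each pair of points. OsMADS3 sits at 24 and 33.8 TPM in the panda libraries and at 0.87 and 0.712 TPM in the WT libraries.

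Across the genome 2357 of 22220 tested genes changed, 701 higher and 1656 lower in panda (limma, adjusted p below 0.05), against 6087 genes at an unadjusted p below that level. The median log2 fold change was 0.73 among the rises and -0.73 among the falls, and 608 of the calls changed by at least 1. The largest rise was that of LOC_Os07g06834 (5.53), at 4.85 and 3.33 TPM in the WT libraries and 236 and 227 TPM in panda, and the largest fall that of LOC_Os09g18594 (-6.65), at 104 and 107 TPM in WT and listed at 0 and 0.117 TPM in panda. Neither has a name here. For each named gene said to have risen or fallen, both panda libraries lay on the same side of both WT libraries. Among all calls this held for 701 of the 701 rises and 1654 of the 1656 falls, so it is no separate support. Over all tested genes the groups did not overlap in 58.1%, against 33.3% by chance.

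The size and balance of these calls depended on scaling and on single libraries. Falls made up 70.3% of the calls as deposited, 59.5% (855 up, 1254 down) with median-ratio scaling and 53% (998 up, 1127 down) with quantile scaling. Without panda replicate 1 the count was 155 and without panda replicate 2 it was 152, and of 72 named calls 4 passed without the former (OsMADS3, OsMADS5, CPS4 and LEA3) and 5 without the latter (the same genes and CYP71Z7). With no filter 40 of the 72 were lost.

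**Figure D2:**
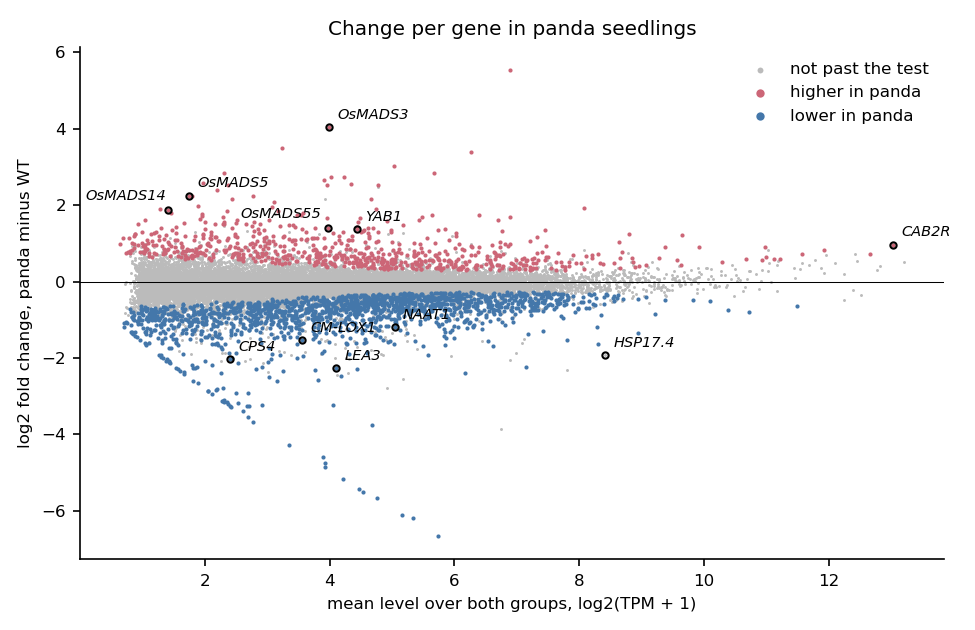
Log2 fold change (panda minus WT) of each tested gene against its mean level in log2(TPM + 1), with genes past the test in red (701 higher in panda) and blue (1656 lower). OsMADS3 stands at 4.04 and LEA3 at -2.27, and HSP17.4 (-1.92) did not pass.

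Most measured genes of diterpenoid phytoalexin synthesis, a branch of defence metabolism, fell in panda. CPS4, the syn-copalyl diphosphate synthase that starts momilactone synthesis, fell from 7.47 ± 0.268 to 1.1 ± 0.514 TPM (SD, n = 2), a log2 fold change of -2.03 ± 0.2 (SE; adjusted p = 0.0082). CYP71Z7, a cytochrome P450 of the phytocassane cluster, fell from 11.4 ± 1.02 to 2.83 ± 1.05 TPM (SD, n = 2). Of 15 measured genes of diterpenoid phytoalexin synthesis 9 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -1.19. The list was shifted down (adjusted p = 0.0013), but adjusted p = 0.65 with an estimated correlation. CYP99A3, CYP76M6, KOL5 and KOL4 fell by 1.43, 1.36, 1.38 and 1.19 on the log2 scale. CYP99A2, MAS and KSL7, chosen after their values were seen, fell by 1.24, 1.28 and 0.92, and the calls of CYP99A2 and MAS were lost with a replicate block (adjusted p = 0.053 and 0.054). CYP99A2 (adjusted p = 0.058 without WT replicate 1) and KSL7 (0.057 without WT replicate 1 and 0.057 without WT replicate 2) also depended on a WT library.

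Jasmonate genes that passed over all genes fell. AOS2, an allene oxide synthase of jasmonate synthesis, fell from 32 ± 3.18 to 12 ± 0.723 TPM (SD, n = 2; adjusted p = 0.0047), and CM-LOX1, a chloroplast lipoxygenase, from 16.6 ± 2.39 to 5.03 ± 0.226 TPM (SD, n = 2; adjusted p = 0.0062). With AOS2 and CM-LOX1, the genes CM-LOX2, JAZ5 and JAMYB made up the 5 falls among 21 measured genes (2 up and 6 down adjusted over the list alone), with log2 fold changes of -1.05, -0.84 and -0.75. JAMYB was chosen after its values were seen and was lost without the trend (adjusted p = 0.059) and with no filter (0.09), and the call of JAZ5 was lost with a replicate block (adjusted p = 0.063) and without WT replicate 2 (0.084). Taken as a list, jasmonate genes did not pass (median -0.09, adjusted p = 0.24).

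Dehydration genes showed strong falls in few members. LEA3, a late embryogenesis abundant protein gene (LOC_Os05g46480, chromosome 5, 26927607 to 26928902), fell from 27.6 ± 3.76 to 4.93 ± 0.47 TPM (SD, n = 2), a log2 fold change of -2.27 ± 0.13 (SE; adjusted p = 0.0022), and RAB16B, a dehydrin gene, from 2.16 ± 0.0978 to 0.254 ± 0.017 TPM (SD, n = 2). DREB1B, a cold-response regulator, measured 6.86 ± 4.94 and 0.677 ± 0.306 TPM (SD, n = 2; adjusted p = 0.051). Of 25 genes of abscisic acid, drought and cold response, 2 fell and 0 rose (6 and 0 adjusted over the list alone), and the list did not pass (median -0.2, adjusted p = 0.74).

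Some cell wall genes fell by smaller amounts. The secondary wall cellulose synthase genes CESA4, CESA7 and CESA9 fell from 99.4 ± 9.59 to 60.6 ± 2.11, from 74.8 ± 6.04 to 49.2 ± 0.514 and from 61.9 ± 7.59 to 39.5 ± 2.22 TPM (SD, n = 2), with adjusted p from 0.013 to 0.025. CESA6 fell by 0.66 on the log2 scale, and CESA8, BC1 and CSLF6, chosen after their values were seen, by 0.43, 0.55 and 0.33. Of 19 measured genes in a list of expansin, cellulose synthase and related wall genes 7 fell, 0 rose and 12 did not pass (11 down and 1 up adjusted over the list alone), with a median of -0.36. The 7 falls are the genes named here, with no expansin among them. The list was shifted down (adjusted p = 0.022), but adjusted p = 0.65 with an estimated correlation and 0.076 without WT replicate 2. Quantile scaling ended the calls of CESA8, BC1 and CSLF6 (adjusted p = 0.062, 0.053 and 0.079), and median-ratio scaling those of CESA8 and CSLF6 (0.062 and 0.063). CESA8 and CSLF6 were lost without WT replicate 1 (0.062 and 0.064), BC1 and CSLF6 without WT replicate 2 (0.085 and 0.081), and all 3 without the trend (0.07 for CESA8 and CSLF6, 0.05 for BC1).

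Genes tied to grain size and panicle branching changed in part. In the grain size list, fixed before the data were examined, the brassinosteroid genes OsBRI1 (the receptor), BRD1 (a synthesis enzyme) and OsBZR1 (a transcription factor) fell from 42.8 ± 1.86 to 29.2 ± 0.903, from 15.3 ± 0.792 to 9.94 ± 0.877 and from 14.8 ± 0.339 to 10.4 ± 0.532 TPM (SD, n = 2; adjusted p = 0.015, 0.031 and 0.036). They were the 3 falls among its 9 measured genes (4 adjusted over the list alone), and the list did not pass (median -0.15, adjusted p = 0.14). Of the 19 loci written for this list 9 are not analysed here. The same 3 genes were the falls among 10 brassinosteroid genes (1 up and 3 down adjusted over the list alone, median -0.19, adjusted p = 0.62). OsSPL13, a grain-length gene, fell from 4.22 ± 0.00256 to 2.26 ± 0.227 TPM (SD, n = 2; adjusted p = 0.033) and was the 1 fall among 7 genes of tillering and panicle branching (2 adjusted over the list alone, median -0.26, adjusted p = 0.057). Of the 17 loci written for tillering and panicle branching 6 are not analysed here. OsSPL13 and SPL2, which fell by 0.62 on the log2 scale, were the changed genes among 11 SPL genes (0 up and 2 down adjusted over the list alone, median -0.14, adjusted p = 0.19). A replicate block ended the calls of BRD1, OsBZR1 and OsSPL13 (adjusted p = 0.051, 0.054 and 0.059), and OsBRI1 kept its call under the block. Quantile scaling ended the calls of OsBZR1 and OsSPL13 (0.066 and 0.051), and median-ratio scaling that of OsBZR1 (0.056). OsBZR1 and OsSPL13 were lost without WT replicate 1 (0.064 and 0.062), and BRD1, OsBZR1 and OsSPL13 without WT replicate 2 (0.081, 0.096 and 0.077).

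The 3 polycomb genes that could be named showed no detected change. The list held 11 loci, and the other 8, whose symbols were not found in the reference table, are not analysed here. OsiEZ1, a histone methyltransferase gene, measured 26.8 ± 0.699 TPM in WT and 25.9 ± 0.0745 TPM in panda, OsMSI1 measured 58.1 ± 1.42 and 58.5 ± 1.37 TPM, and OsLHP1 measured 29.6 ± 0.519 and 28.7 ± 0.53 TPM (SD, n = 2 each). Their log2 fold changes were -0.05 (95% interval -0.22 to 0.13), 0.01 (-0.15 to 0.17) and -0.04 (-0.21 to 0.13). In this list of 3 measured genes, fixed before the data were examined, 0 passed in limma over all genes, 0 adjusted over the list alone, 0 at an unadjusted p below 0.05 and 0 in limma-voom, and camera gave adjusted p = 0.89, with a median of -0.04 and a test direction of up.

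Several chlorophyll synthesis and light-harvesting genes rose. CHLP and CHLH, which act in chlorophyll synthesis, rose from 304 ± 41.6 to 518 ± 5.75 TPM and from 231 ± 24.8 to 357 ± 5.93 TPM (SD, n = 2; adjusted p = 0.017 and 0.019). PORB rose by 0.47 on the log2 scale (adjusted p = 0.066 without the trend and 0.092 with no filter), and SGR, a gene of chlorophyll breakdown, fell by 0.57. The light-harvesting genes CAB2R and CAB1R, chosen after their values were seen, rose from 5700 ± 996 to 11000 ± 377 and from 4920 ± 206 to 8060 ± 609 TPM (SD, n = 2; adjusted p = 0.036 and 0.044), but not with quantile scaling (0.095 and 0.058) or a replicate block (0.066 and 0.085), and CAB1R also not with median-ratio scaling (0.054). RBCS, the small subunit of Rubisco, chosen in the same way, measured 5680 ± 514 and 4080 ± 190 TPM (SD, n = 2; adjusted p = 0.1). These 3 belong to families with close copies, so their levels are uncertain. Of 27 genes of photosynthesis and chlorophyll 6 rose (among them PSY1, chosen after its values were seen and lost with adjusted p = 0.089 without WT replicate 2 and 0.09 without the trend) and 1 fell (7 and 3 adjusted over the list alone), and the list was shifted up by a median of 0.1 (adjusted p = 0.022). It had adjusted p = 0.5 with an estimated correlation, 0.32 with quantile scaling and 0.063 without panda replicate 1.

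Cell cycle and cytokinin lists shifted up through many small differences. Of 15 cell cycle and replication genes 13 had a positive log2 fold change, but MCM4, part of the replicative helicase, was the 1 that passed (2.3 ± 0.208 to 4.46 ± 0.256 TPM, SD, n = 2; adjusted p = 0.029, 0.056 with a replicate block and 0.057 without WT replicate 1), with 3 up adjusted over the list alone. The list had a median of 0.3 and adjusted p = 5.7e-06, but adjusted p = 0.5 with an estimated correlation and 0.12 with the filter of 5 TPM. Of 13 cytokinin genes 3 rose and 0 fell (3 and 0 adjusted over the list alone): the response regulator RR11 by 0.89 (adjusted p = 0.064 with a replicate block and 0.06 without WT replicate 1) and the cytokinin oxidases CKX4 and CKX9, which break the hormone down, by 0.66 and 0.61 (0.066 for CKX4 without WT replicate 2). That list had a median of 0.2 and adjusted p = 0.0017, and adjusted p = 0.5 with an estimated correlation. RR11 passed the filter only through the panda libraries.

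In the flowering time and clock list, fixed before the data were examined, OsMADS14 was the 1 rise among 7 measured genes (1 adjusted over the list alone, median 0.12). It was shifted up with adjusted p = 0.018, but adjusted p = 0.5 with an estimated correlation, 0.066 with quantile scaling and 0.11 with the filter of 5 TPM. OsMADS14 passed the filter only through the panda libraries. The 5 sugar transport genes, of which SWEET14 rose from 10.4 ± 0.191 to 14.4 ± 0.213 TPM (SD, n = 2; adjusted p = 0.062 with a replicate block, 0.08 without WT replicate 1 and 0.081 without WT replicate 2), had a median of 0.24 (adjusted p = 0.03) and adjusted p = 0.5 with an estimated correlation. Sugar transport was past the threshold neither with quantile scaling (0.066) or no filter (0.083) nor without panda replicate 1 (0.052), panda replicate 2 (0.055) or WT replicate 1 (0.055).

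**Figure D3:**
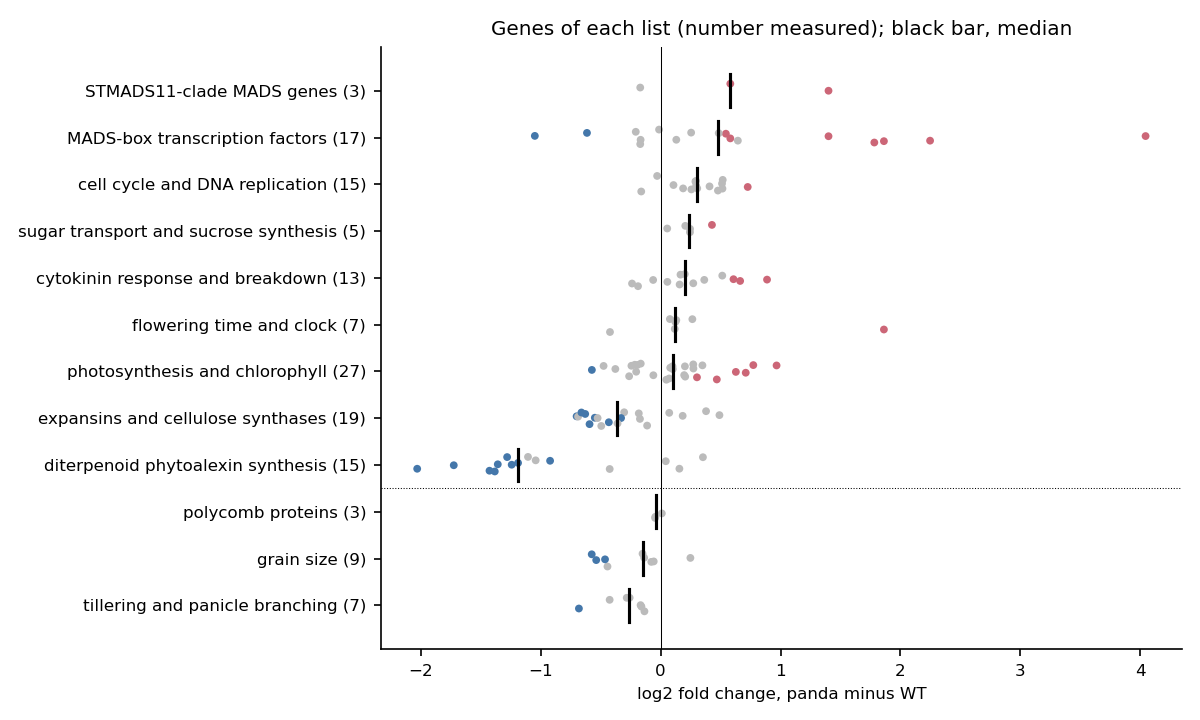
Log2 fold change (panda minus WT) of each measured gene in the 9 lists past the test and in 3 lists fixed before the data were examined that did not pass (under the dotted line). Black bars are medians, from 0.58 for the STMADS11 clade to -1.19 for diterpenoid phytoalexin synthesis, and grey points did not pass.

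Changed genes lay side by side more often than by chance. Adjacent tested genes changed in the same direction in 323 pairs, against a mean of 145 and a maximum of 188 over 10000 shuffles, 2.22 times the mean (permutation p = 1e-04, one-sided, the smallest the shuffles can give). Of 57 runs of at least 3 genes, 43 were lower in panda. CPS4, CYP99A3, MAS and CYP99A2 lay in a run of 5 falling genes on chromosome 4 (5318060 to 5486773), CM-LOX1 and CM-LOX2 in a run of 4 falling genes on chromosome 8 (25216363 to 25266935), and DL and OsMADS1 in a run of 3 rising genes on chromosome 3 (6041245 to 6084525). Runs of 6 rising genes on chromosome 4 (5920297 to 6232479) and of 9 falling genes on the same chromosome (9153929 to 9160548) hold no gene with a name here. The latter is 1 of 6 dense runs, with under 1.5 kb of chromosome per gene (a bound set after the data were seen). All 6 were lower in panda, with 32 genes on 1.6 to 6.6 kb each and log2 fold changes from -0.8 to -0.47. Their levels are uncertain, and whether they share reads with organelle sequences could not be looked at without a genome sequence. Without these genes 297 pairs were counted against a shuffled mean of 141 (2.11 times, permutation p = 1e-04), and 37 of the 51 other runs were lower in panda.

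A set of genes expressed in WT was near silent in panda. By thresholds set after the data were seen (at least 2 TPM in both libraries of one genotype and at most 0.2 TPM in both of the other), 40 genes were expressed in WT alone and 4 in panda alone, among them OsMADS5 and OsMADS14. The other ways of splitting the 4 libraries into pairs gave 0 and 2 such genes. Pairs of libraries are too few for a test of this count.

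**Figure D4:**
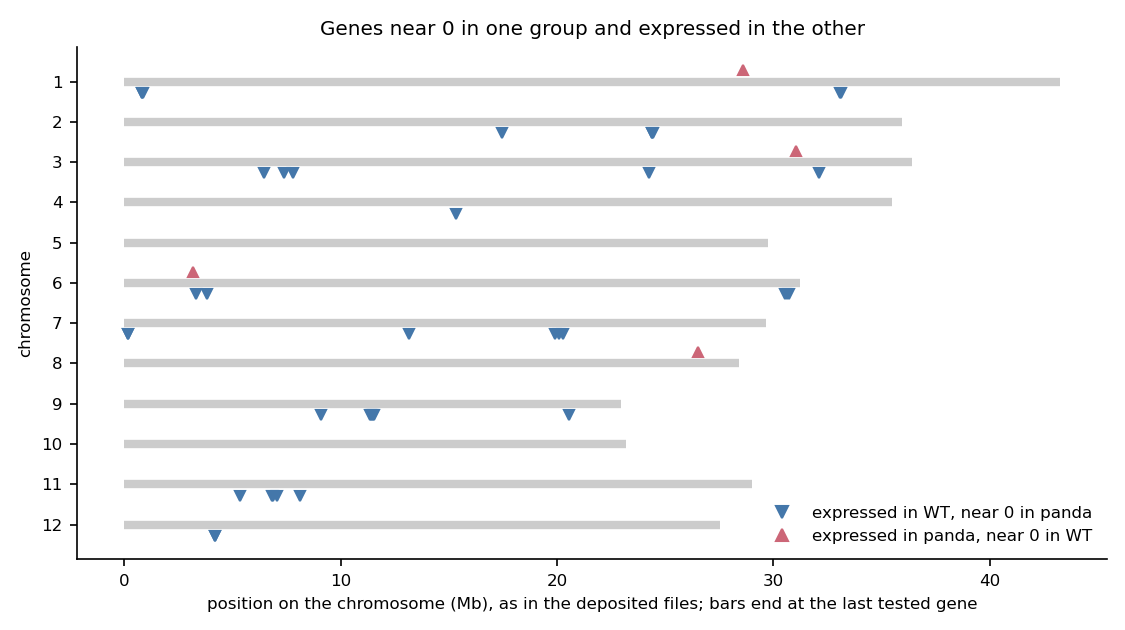
Positions in Mb, as in the deposited tables, of the 40 genes expressed in WT and near 0 in panda (blue) and the 4 with the opposite pattern (red) on the 12 chromosomes. Several blue marks lie close together, as on chromosomes 1, 2, 7, 9 and 11.

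WT replicate 2 stood apart in heat shock genes. Of 15 measured heat shock genes 13 were highest in that library, and 10 were over 5 times higher there than in any other. HSP17.4, a small heat shock protein gene chosen after its values were seen, measured 1260 TPM there, 4.23 TPM in WT replicate 1 and 89.2 and 4.08 TPM in the panda libraries. HSP26.7, CLPB1 and HSP17.7, chosen in the same way, also differed between the panda libraries. They measured 6.48, 5.62 and 31.7 TPM in panda replicate 1 and 0.0433, 0.45 and 2.13 TPM in panda replicate 2. HSFA2E, also chosen in this way, did not (47.4 and 48.7 TPM). Of the 15 genes 0 passed in limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05, 0 in limma-voom), and the list did not pass (median -1.6, adjusted p = 0.38). Its median was -3.76 without WT replicate 1 (adjusted p = 5.7e-05) and 0.47 without WT replicate 2 (0.076). OsLHY, a clock gene chosen after its values were seen, was also highest in WT replicate 2, at 47.7 TPM against at most 23 TPM in each of the others. Without that library 1824 genes changed, 575 up and 1249 down, and the gene lists past the threshold numbered 11 in place of 9.

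**Figure D5:**
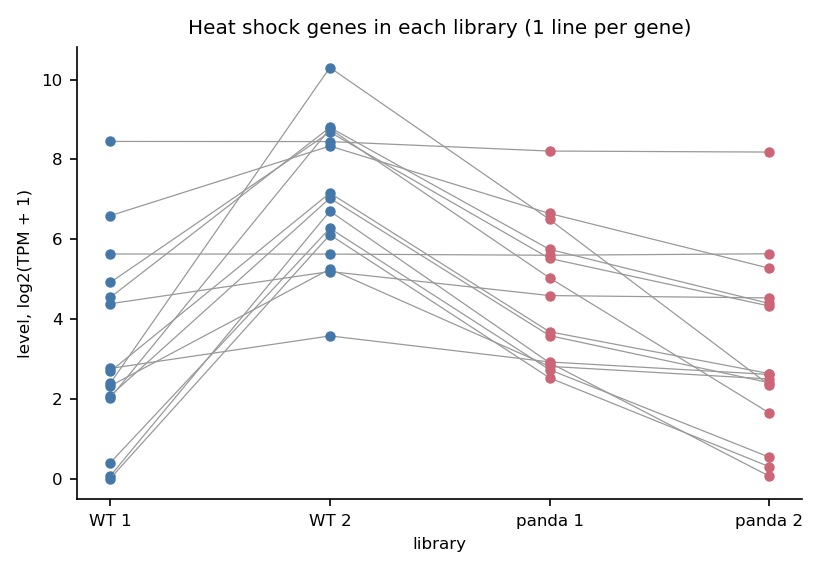
Level in log2(TPM + 1) of the 15 measured heat shock genes in each library, with 1 line per gene, WT in blue and panda in red. In WT replicate 2, 13 of the 15 genes had their highest level.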

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

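The crossed block and the counts of neighbours that do not overlap or without dense runs were chosen only after the result was seen. Of 2357 changed genes as reported, 608 changed by at least 1 on the log2 scale. With no filter 37968 genes were tested and 940 called, 865 of them among the 2357. Leaving out 1 library gave 152 to 2734 (lowest without panda replicate 2, then 155 without panda replicate 1), with a lone library assumed to vary like the other group. The other alternatives gave 1673 to 2622, and no gene called as reported was called in the opposite direction under any. The list count of 9 became 5 with quantile scaling and 0 with an estimated correlation, where the lowest adjusted p was 0.5, and ran from 7 to 11 otherwise, also over the libraries left out. With every library kept, neighbouring pairs numbered 1.92 (filter of 5 TPM) to 5.78 (no filter) times their shuffled mean. Pairs that do not overlap stood at 2.23, and those without dense runs at 2.11. Ratios with a library left out are not given, since those without a panda library rest on few pairs.

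With the replicate number as a block 2154 genes and 8 lists were called, and the neighbour ratio was 2.31. Nothing in the labels pairs the libraries, and same-numbered libraries deviated with a correlation of -0.12. With the numbers crossed, 1673 genes and 11 lists were called. The block ended the STMADS11-clade call (0.06) and 15 of 72 named calls, and no other list call. Of the 72 named calls, 40 were lost with no filter, 10 with median-ratio and 14 with quantile scaling, 10 without the trend, 18 without WT replicate 1, 15 without WT replicate 2, 68 without panda replicate 1 and 67 without panda replicate 2; none reversed in any alternative. Apart from fewer libraries or more tested genes, the cause was not tested. The WT libraries lay over 1 apart on the log2 scale in 291 tested genes, the panda libraries in 106. A fit without a panda library took its spread from the WT pair alone, which varied more. Genes under 5 TPM have no value under that filter. At 12.0 to 18.2 read pairs for 1 TPM on 1 kb, levels of genes near 1 TPM rest on few reads.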

Other observations

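The tests of contiguous deletions, all 3 tests of the flower genes and the tests of the falls by scaling and without the 100 most abundant genes were chosen only after the result was seen; the tests of depth, of another haplotype and without the 10 most abundant genes were written before their results.

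Several smaller gene groups moved both ways or in single members. Of 9 measured pathogenesis-related and chitinase genes, the chitinase genes Cht4, Cht5 and Cht6 rose, from 50.5 ± 10.4 to 154 ± 17, from 17 ± 3.81 to 44.5 ± 5.87 and from 13.4 ± 0.0296 to 21.3 ± 0.0488 TPM (SD, n = 2), while Cht1 fell from 29.6 ± 3.38 to 19.2 ± 0.23 TPM (adjusted p = 0.053 with quantile scaling). Adjusted over the list alone 3 rose and 5 fell, and the list did not pass (median -0.26, mean -0.01, test direction up, adjusted p = 0.74). Among 24 auxin response genes IAA31 and IAA18 rose by 0.79 and 0.74 on the log2 scale, and IAA6, IAA1 and IAA15 (the last chosen after its values were seen) fell by 0.77, 0.46 and 0.52 (adjusted p of IAA15 0.052 with median-ratio and 0.06 with quantile scaling, 0.064 without the trend and 0.06 without WT replicate 1), with 4 up and 5 down adjusted over the list alone and no shift of the list (median -0.12, mean -0.07, test direction up, adjusted p = 0.78). The tonoplast aquaporin genes TIP1-2 and TIP2-2 moved apart, from 182 ± 8.8 to 296 ± 22 TPM and from 360 ± 33.2 to 238 ± 9.64 TPM (SD, n = 2), in a list of 13 that did not pass (2 up and 1 down adjusted over the list alone, median 0.01, adjusted p = 0.27). NAAT1, an enzyme gene of phytosiderophore synthesis, fell from 44.8 ± 4.39 to 19.1 ± 0.196 TPM (SD, n = 2; adjusted p = 0.0048) and was the 1 fall among 8 iron genes (3 adjusted over the list alone, median -0.24, list adjusted p = 0.054).

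SPX2 was the 1 rise among 9 phosphate genes (1 adjusted over the list alone, median 0.01, adjusted p = 0.24), but with adjusted p = 0.058 without WT replicate 1 and 0.062 without WT replicate 2. GLN1-2 was the 1 fall among 8 nitrogen genes (1 adjusted over the list alone, median 0.06, adjusted p = 0.24), but its call was lost with median-ratio (adjusted p = 0.066) and quantile scaling (0.082), without the trend (0.06), and without WT replicate 1 (0.072) or 2 (0.09). DNG701 (adjusted p = 0.06 with a replicate block, 0.056 with median-ratio and 0.072 with quantile scaling, 0.084 without WT replicate 1 and 0.092 without WT replicate 2) was the 1 fall among 12 genes of DNA methylation, histone demethylation and small RNA (1 adjusted over the list alone, median -0.03, mean -0.02, test direction up, adjusted p = 0.67). In limma 0 genes passed among 10 gibberellin genes (0 adjusted over the list alone, 2 at an unadjusted p below 0.05, 1 in limma-voom; median -0.13, adjusted p = 0.81). Likewise 0 passed among 9 WRKY and immune regulator genes (2 down adjusted over the list alone, 3 unadjusted, 1 in limma-voom; median -0.09, adjusted p = 0.55) and 17 clock and photoreceptor genes (0 over the list alone, 1 unadjusted, 0 in limma-voom; median -0.06, mean -0.05, test direction up, adjusted p = 0.74). Markers of other organs were few: of 4 measured seed genes 0 passed (0 over the list alone, 0 unadjusted, 0 in limma-voom; median -0.01, mean 0.33, test direction up, adjusted p = 0.67). AMY3D, a starch amylase gene chosen after its values were seen, lay at 12.4 TPM in panda replicate 1 and at 0.19, 2.15 and 1.09 TPM in the other libraries. Of 2 measured root markers, too few for a list test and fixed before the data were examined, the silicon channel gene Lsi1 rose from 9.47 ± 1.69 to 16.1 ± 0.084 TPM (SD, n = 2; adjusted p = 0.033; 1 passed adjusted over the list alone).

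The 40 genes expressed in WT and near silent in panda, against 4 the other way, raise the question of a gap in the data or in the genome. At the WT level a panda library would hold a median of 155.2 read pairs of such a gene, which argues against lower depth. Of 48 genes expressed in WT that lie between neighbouring lost genes under 200 kb apart, 83.3% (40) stayed over 1 TPM in both panda libraries. This argues against spanning deletions as the account of all these places, but the count is pooled over them. It says nothing where no expressed gene lies in between. On chromosome 2 (24390731 to 24435197) the lost genes form a run of 3 adjacent tested genes, all listed at 0 in panda. A deletion there stays open, and losses of single genes were not tested. Other tested genes within 100 kb of a lost gene passed the test 1.84 times as often as genes around random ones (18.5% of 356 against 10.1%, permutation p = 0.001 over 1000 draws, the smallest they can give). The random genes were drawn whether changed or not, and changed genes also lay side by side away from the lost genes. There 285 pairs stood against a shuffled mean of 134 (2.13 times, permutation p = 1e-04). The ratio of 1.84 therefore cannot tell stretches of another haplotype in the panda line from this general clustering. Such stretches stay a candidate explanation, and they might also add to the runs of neighbours. Silencing through the mutation itself stays open and untested, since it could also reach neighbouring genes.

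The rise of OsMADS3, OsMADS5, OsMADS14 and OsMADS1 was weighed against 3 technical explanations. Over the scaling alternatives their lowest log2 fold change was 1.33, which argues against scaling between libraries. Of 11 other flower genes, 2 gained at least 10% of the mean gain of 9.64 TPM, a bar set mostly by OsMADS3 (28.1 TPM). Among the rest OsMADS7 and OsMADS8 gained 0 TPM, and the gain of OsMADS16 was -3.65 TPM. This argues against an addition of flower tissue that expresses these genes. OsMADS21 and OsMADS34, outside the 11, lay higher in panda at low levels. A small amount of other flower or inflorescence tissue therefore cannot be excluded by this count. The summed loss of their 7 nearest relatives was -0.0122 TPM against a gain of 38.6 TPM, which argues against reads taken from those relatives. As a hypothesis found on the same data, the rise may reflect the mutation, which was not tested, nor was a difference in the genetic background for these genes.

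The excess of falling genes (70.3% of the calls) was weighed against the way levels are scaled. With the 10 most abundant genes left out, 2247 genes changed (751 up, 1496 down) and 66.6% of them fell, but these genes hold only part of the difference in shares (7.3 and 7.49% of the total in panda, 6.03 and 5.52% in WT), so this value excludes nothing. With the 100 most abundant genes left out, which took 23.6 and 23.9% in panda and 20.6 and 18.9% in WT, 2108 genes changed (869 up, 1239 down) and 58.8% of them fell, so a larger share of abundant genes is a candidate explanation for part of the excess. Falls made up 59.5% of the calls with median-ratio scaling and 53% with quantile scaling, so a general lowering of many genes in panda and an effect of scaling cannot be told apart, because TPM carries no absolute amount of RNA.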
